A study of Mus musculus with 3 samples.

How the data were processed

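The series measured DNA methylation in mouse frontal cortex by methylated DNA immunoprecipitation followed by array hybridisation. Per the labels' protocols, 3 DNA pools were made, each from 3 naive male C57BL/6 mice of 2 months of age. From each pool 2 µg of DNA was sonicated, and methylated fragments were captured with 10 µg of an antibody against 5-methylcytosine that is described as not recognising hydroxymethylated DNA, and with 50 µl of protein G. The input and the bound (immunoprecipitated) fraction were both amplified by whole-genome amplification, which can itself distort the representation of sequences. Input DNA was labelled with Cy3 and the bound fraction with Cy5, and both fractions of a pool were hybridised to 1 array, in the same dye orientation on all 3 arrays, so a dye effect cannot be separated from enrichment. The sample titles number the replicates 1 to 3 and the protocol speaks of triplicate pools, but the sample descriptions give the same replicate number, 1, to every array. The titles were followed and each array was used as 1 pool and 1 replicate. If arrays shared a pool, every SD and p-value would cover the spread between arrays and not between pools. There was 1 group and no second condition, so every comparison is of bound with input DNA, or of parts of the genome with each other.

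The scanner files hold intensities of 420288 spots per array, of which 4474 were control spots. Per the file headers, they were made with Agilent Feature Extraction 10.7.3.1 on a custom design placed on mouse build mm9 (NCBI37). Per the file headers, the processed intensities are background-subtracted, spatially detrended and dye-normalised with 1 linear factor per channel, and signals near background are replaced by surrogate values. Per the file headers, a column of log10 ratios gives red over green (Cy5 over Cy3) processed signal, and its values are 0 where both channels are near background. The series matrix deposited by the authors holds log2 ratios of the same spots. These tracked log2 of bound over input background-subtracted spot medians (r = 0.999 or more over spots on each array), were missing where such a median was 0 or below, and had column medians of -0.97, -0.97 and -0.97. Its direction was therefore bound over input. How it was normalised is not given in the sources used here, and its centring was not on 0.

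The log2 ratio of bound over input processed signal was taken per spot, spots flagged as outliers were left out, and each array was centred on the median of its non-control probes. No loess or quantile step was used, because on such an array many probes can truly shift one way. Before centring the medians were -0.19, -0.19 and -0.09. The 6208 probes spotted more than once were averaged, which left 409606 distinct probes of 45 to 60 nt. Of these, 9 lay on unplaced sequence and were left out, and 409559 had a value on all arrays. A value of 0 is thus the median probe of the array and not an unmethylated or methylated reference, and a call says that a probe or region was more or less enriched than that median. Enrichment by this antibody also rises with the number of methylated CpGs in a fragment, so a log2 ratio is not a methylation percentage.

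Each test was limma's 1-group fit against 0 with empirical Bayes variances and Benjamini-Hochberg adjustment at 0.05 (limma 3.58.1, R 4.3.3). Differences between classes of regions were taken per array and tested with an exact two-sided sign-flip permutation test, for which 3 arrays allow no p below 0.25. The promoter, transcription start site, CpG class, TATA box and gene list comparisons fixed before the data were examined were not made. The files give probes by mm9 position and without gene names, the only annotation used here is of another build, and no genome sequence or probe sequence was used. In their place, probes were joined into tiled regions, which are runs of probes whose starts lie at most 500 bp apart, with at least 3 probes. These regions, the contrast of centre and edges, the length classes and the windows were chosen after the data were seen. Standard regions were 1000 to 1800 bp long with at least 8 probes where the centre was compared with the edges. The centre was taken as probes within 200 bp of the region's midpoint and the edges as those more than 500 bp from it, with at least 2 probes in each. Short regions were at most 600 bp long and long ones over 1800 bp. Of the comparisons fixed beforehand, the test per probe and the comparison of the X chromosome with the autosomes were made, the latter on tiled regions.

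Named items followed the rule fixed for genes, carried over to regions, which took the 10 highest and the 10 lowest values past the threshold with the same sign on all 3 arrays and at least 3 probes. Parts of that rule about gene names and families could not be used. Because values at the background floor have no order, regions were ranked only where every probe was well above background in each channel on at least 1 array. The array could differ between the channels, here and wherever this rule for ranking is named below. Of 18916 called regions with 1 sign on all arrays, 2809 met the rule, 2384 higher and 425 lower. For centre minus edges 750 of 8707 did. No single probe was named.

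Input spots well above background made up 83.3%, 69.0% and 69.3% of spots on replicates 1, 2 and 3, and bound spots 65.9%, 47.3% and 51.0%. The scanner software's signal-to-noise values were 20.3, 11.0 and 10.9 for input and 9.93, 4.44 and 5.22 for bound DNA, outside the software's accepted range on all arrays. Probes spotted more than once had an SD between spots of 0.47, 0.53 and 0.53 (log2), and of 0.22, 0.23 and 0.24 where both channels were above background. Both channels were above background on all arrays for 173308 probes, and below it on all arrays for 58486. The latter have no measured ratio, and their surrogate values gave a mean log2 ratio of 0.35 ± 0.14 (SD, n = 3 arrays).

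The fit was tested on simulated data with independent normal noise, scaled by the empirical Bayes variances of the real fit. Effects shared by many features of an array were not simulated, so recovery and false calls in the real data can differ. With 200 of 409559 probes changed, it recovered 0% of those changed by 1, 16% of those changed by 2 and 96% of those changed by 3 (log2). With 200 of 28880 regions changed it recovered 50% at 0.5 and 100% at 1 or more, and with 200 of 18326 centre minus edge differences changed, 6% at 0.5, 50% at 1 and 100% at 2. In that last simulation 19 of 147 calls were false, 12.9%, and for regions 12 of 187 were, 6.42%. With every second feature changed, recovery at 1 was 80.6% for probes, 100% for regions and 91.8% for centre minus edges, and false calls were 2.6%, 2.54% and 2.17% of all calls.

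Alternatives were normexp background correction on spot medians (offset 50; the files used hold no spot means), loess within arrays, the series matrix values, each array left out, filters on dim probes, centring on the mode, a log2 ratio of at least 0.5, the scanner's log ratio column, removal of a trend with probe length, other region definitions and array weights. Alternatives that need sequence or an annotation were not run.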

Results

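Methylated DNA was profiled in frontal cortex of adult male mice on a tiling array, to map where 5-methylcytosine lies around the tiled sites. The series title places the data in a study of methylation at transcription start sites and its relation to the binding of the TATA-binding protein. The data were 3 arrays of 1 group, each comparing immunoprecipitated with input DNA of a pool of 3 mice, with 420288 spots per array. All values are log2 ratios of bound over input DNA relative to the array's median probe, positions are on mouse build mm9, and errors are SDs over the 3 arrays unless stated. With 3 arrays the precision of every value is limited by their number. Across probes the arrays correlated with Pearson's r of 0.73 to 0.77, and with 0.90 to 0.91 over the 173292 probes above background in both channels. Across tiled regions r was 0.90 to 0.93. These are correlations across features of the genome, which are not independent replicates.

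The first question was which sites carried more or less immunoprecipitated DNA than the median site. Of 28880 tiled regions, with a median of 14 probes over 1341 bp, 8066 (27.9%) were higher than the array median and 11003 (38.1%) were lower (limma, adjusted p under 0.05). A difference of at least 2-fold was reached by 2552 of the higher and 2348 of the lower regions. Region means ran from -1.15 at the 5th percentile to 1.30 at the 95th, with a median SD over arrays of 0.19 per region. The sign was the same on all 3 arrays for 79.3% of regions. The split into higher and lower depends on the zero point. The mode of each array's distribution lay 0.70, 0.81 and 0.64 above its median, and with the mode as zero 2500 regions were higher and 22219 lower.

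At single probes, 91777 of 409559 (22.4%) were higher and 96483 (23.6%) lower. The corresponding numbers were 31931 and 168205 with the mode as zero, and 100763 and 60821 with the series matrix values. Of the higher probes, 14221 were below background in both channels on all arrays, and so were 1071 of the lower ones. These have no measured ratio. With such probes removed and the arrays centred again, 91274 probes were higher and 87962 lower, whereas removal without a new centring left 77556 higher and 95412 lower. A further 34474 of the lower probes were below background only in the bound channel on all arrays, for which the ratio is an upper limit. Likewise, 10563 of the 11003 lower regions held at least 1 probe with bound DNA below background on all arrays, and 4412 of the 8066 higher regions at least 1 probe below background in both channels. Bound DNA was below background on all arrays for 129759 of 409597 placed probes. Regions of any call can thus hold such a probe, and the share over all regions is not given here. Leaving out replicate 2 lowered the higher probes to 42611 and the lower ones to 58484, and leaving out replicate 3 gave 54585 and 62419. Without replicate 1 the numbers were 63220 and 86474. A fit on 2 arrays has fewer degrees of freedom, so fewer calls need not reflect the array left out. Over the 173292 probes above background in both channels, 58451 were higher and 60607 lower. For these counts the arrays were centred again on those probes, which moved the zero up.

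The highest region among those ranked, in which every probe was above background in both channels on at least 1 array, lay on chromosome 6 from 78165841 to 78166072, where bound DNA was 15-fold above the median probe (log2 3.90 ± 0.19, n = 3, 4 probes, limma adjusted p = 1.57e-08). Its log2 ratio was 3.01 with normexp and 2.85 with loess. It was followed by chromosome 11 from 95993918 to 95994121, at 3.60 ± 0.28 over 3 probes. The longest stretches among the 10 highest were 1063 bp of chromosome 6, from 29100834 to 29101896, with 3.41 ± 0.25 over 12 probes, and 1416 bp of chromosome 2, from 172944807 to 172946222, with 3.28 ± 0.23 over 15 probes. The other 8 were at most 305 bp long and had 3 or 4 probes each. In addition to the first 2 named here, these short regions were on chromosomes 15 (78299981 to 78300240, 3.37 ± 0.14), 12 (86286160 to 86286464, 3.37 ± 0.22), 11 (5802982 to 5803282, 3.35 ± 0.03), 14 (41028539 to 41028724, 3.30 ± 0.22, with 10 of 12 input measurements above background and 2.17 with normexp), 7 (112098687 to 112098949, 3.29 ± 0.44) and 2 (168094618 to 168094844, 3.27 ± 0.11). All 10 had limma adjusted p values of 4.1e-08 or lower and were higher in 3 of 3 arrays. A rule that every probe be above background is met more easily by regions with few probes, so the ranking favours short regions. Of the 28880 regions tested 3143 were short (at most 600 bp), yet only 3 of the 20 named regions, higher and lower, had at least 8 probes.

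The lowest value among regions ranked was on chromosome 11 from 58660518 to 58660784, with a log2 ratio of -2.67 ± 0.81 (n = 3, 3 probes, limma adjusted p = 1.29e-06). Its bound signal was well above background in 5 of 9 probe measurements, so the value rests in part on surrogate signals. It was -1.30 with normexp, and other regions were lower with normexp, with loess and without replicate 2. Another on chromosome 11, from 115375530 to 115375967, was at -2.60 ± 0.44 over 6 probes, with 14 of 18 bound measurements above background. The region from 60097852 to 60097965 on chromosome 4 was at -2.0 ± 0.16 over 3 probes, and that from 46480828 to 46481106 on chromosome 7 at -1.89 ± 0.28 over 3 probes, both with every bound measurement above background. The longest of the 10 lowest covered 1129 bp of chromosome 7, from 39101632 to 39102760, at -1.97 ± 0.07 over 9 probes, with 26 of 27 bound measurements above background. The remaining 5 lay on chromosomes 4 (143202443 to 143202666, -2.21 ± 0.11, 10 of 12 bound measurements above background), 2 (176194714 to 176195203, -1.84 ± 0.32, 6 of 9), 9 (57288932 to 57289135, -1.82 ± 0.47, 4 of 9), 7 (13482959 to 13483425, -1.82 ± 0.23, 15 of 18) and 10 (88289355 to 88289658, -1.78 ± 0.45, 11 of 12). With normexp the region on chromosome 9 was at -0.78. All 10 were lower in 3 of 3 arrays, with limma adjusted p values of 1.94e-06 or lower. The 10 higher and 10 lower regions were chosen as extremes of these same arrays, so a reversal was unlikely. They kept their direction and stayed past the threshold in every alternative that could be computed for them, but their sizes and order did not hold. With loess, for example, the 1063 bp stretch of chromosome 6 was at 1.94. Bound DNA below background cannot be ranked, so regions with less bound DNA than these are not in this list.

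**Figure D1:**
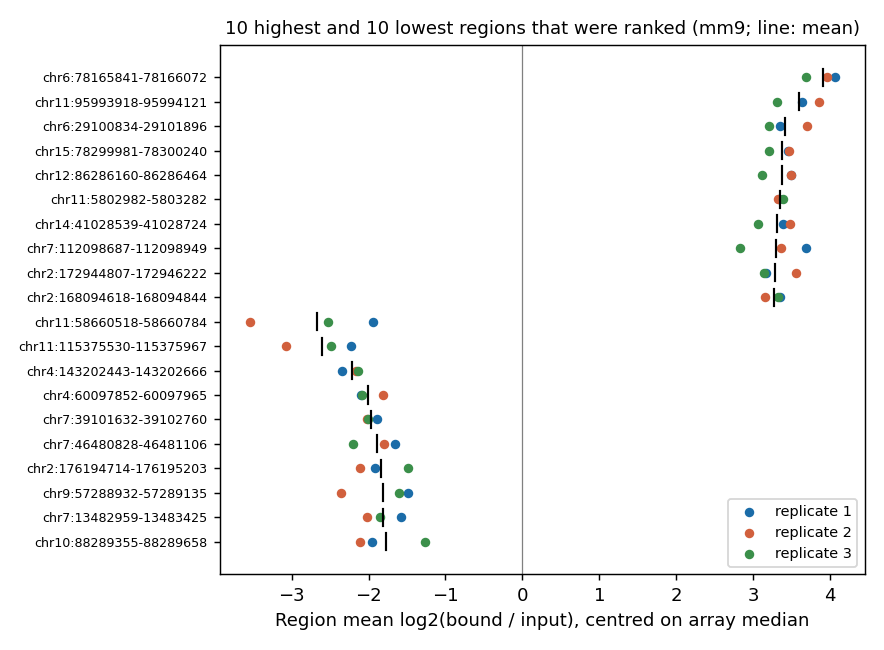
Region mean log2 ratio of bound over input DNA on the x axis for the 10 highest and 10 lowest of the regions ranked (y axis, mm9 positions). Points are the 3 replicates and black lines their means, and all higher regions lie between 2.83 and 4.06 while all lower ones lie between -3.54 and -1.26.

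The second comparison asked whether enrichment differed along a tiled region, which the array design made possible because 19765 of the 28880 regions were 1000 to 1800 bp long. In standard regions the centre carried less bound DNA than the edges. Over 18326 regions the centre averaged -0.19 ± 0.04 and the edges 0.10 ± 0.05, a difference of -0.29 ± 0.08 (n = 3), present on all arrays (-0.38, -0.25 and -0.24). The exact two-sided sign-flip permutation test gave p = 0.25, the smallest that 3 arrays allow. In single regions, the centre was lower than the edges in 6131 (33.5%) and higher in 2685 (14.7%) by limma's test, and by at least 2-fold in 4081 and 1417. Leaving out replicate 2 lowered the number with a higher centre to 1525, and leaving out replicate 1 or 3 lowered it to 2415 or 2022. Over probes with both channels above background the numbers were 2610 and 1378. Fewer regions kept enough probes under that filter, and their number is not given here. The mean difference under it was -0.298 (SD 0.03). With normexp correction the mean difference was -0.13. Whether the midpoint of a region is a transcription start site was not analysed here.

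Mean enrichment rose stepwise away from the midpoint. It was -0.20 ± 0.04 within 100 bp, -0.13 ± 0.02 at 200 to 300 bp, 0.05 ± 0.03 at 400 to 500 bp and 0.11 ± 0.05 at 600 to 700 bp. Over probes with both channels above background on all arrays, which also selects on bound signal, the corresponding values were 0.26 ± 0.11, 0.35 ± 0.13, 0.53 ± 0.14 and 0.57 ± 0.15. With only input above background they were -0.34 ± 0.08, -0.245 ± 0.09, -0.002 ± 0.12 and 0.085 ± 0.13. The level at the centre thus depended on the selection, while the rise was present in each.

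**Figure D2:**
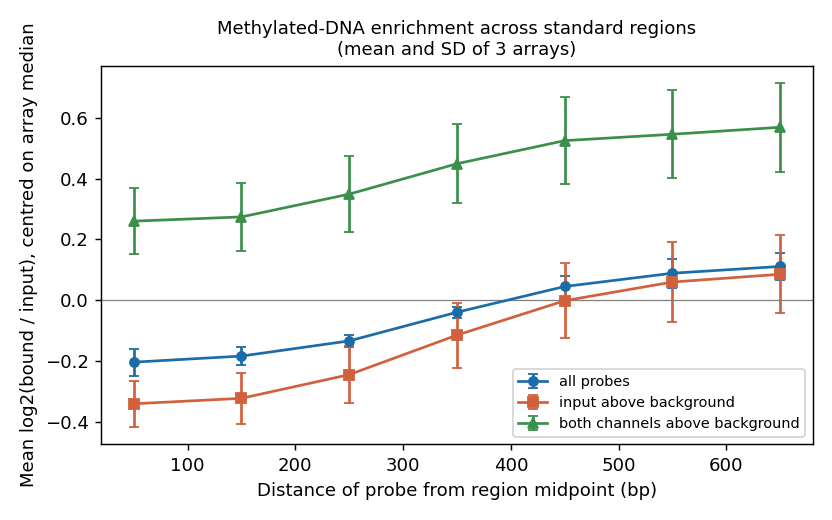
Mean log2 ratio of bound over input DNA (y axis) by distance of the probe from the midpoint of standard regions in bp (x axis), in bins of 100 bp, for 3 selections of probes. Points are means and bars SDs of 3 arrays, and each selection rises from the centre to 600 to 700 bp, from -0.20 to 0.11 for all probes.

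Among regions in which every probe was above background in both channels on at least 1 array, the lowest centre relative to the edges was on chromosome 6 from 39507750 to 39509091, where the centre was at -1.14 ± 0.49 and the edges at 1.45 ± 0.21, a difference of -2.59 ± 0.29 (n = 3, limma adjusted p = 2.69e-05), with 30 of 36 bound measurements above background. With normexp this difference was -1.12, smaller in size than that of other regions such as chromosome 2 from 153623192 to 153624550 (-1.59, against -2.34 ± 0.32 with the processed signals and -0.65 with loess). Another on chromosome 6, from 29420241 to 29421612, differed by -2.35 ± 0.20, with 25 of 30 above background. On the X chromosome the region from 34793664 to 34795194, with all 54 bound measurements above background, had a centre of -0.92 ± 0.28 and edges of 1.27 ± 0.29. The opposite shape was found on chromosome 15 from 84549359 to 84550667, with 46 of 48 bound measurements above background and a centre of 2.53 ± 0.36 against edges of -0.49 ± 0.22, a difference of 3.02 ± 0.47 (limma adjusted p = 2.22e-05), which was 1.84 with loess. It was the largest of its kind with the processed signals, but that on chromosome 3 from 120985875 to 120987185 was larger with loess, at 2.76, and without replicate 2, at 2.93, and another was larger with normexp. On chromosome 7, from 26154526 to 26155931, both parts were enriched, the centre at 3.57 ± 0.10 and the edges at 1.02 ± 0.10. The 10 regions with the lowest centres differed by -2.59 to -2.19 and the 10 with the highest by 2.28 to 3.02, each with the same sign on 3 of 3 arrays.

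The third comparison was of regions of different tiled length. Short regions, 3143 of them with a median of 5 probes, averaged 0.13 ± 0.04 and were higher in 37.1% and lower in 30.5%. The 19765 standard regions averaged -0.04 ± 0.02, with 28.1% higher and 36.8% lower. The 3099 long regions averaged -0.30 ± 0.01, with 15.8% higher and 54.5% lower. Short regions exceeded standard ones by 0.17 ± 0.03 and long ones fell below them by -0.26 ± 0.03 (n = 3 arrays each, exact sign-flip permutation p = 0.25, the smallest possible). The excess of short regions ranged from 0.07 with loess to 0.35 over probes with both channels above background, and the shortfall of long ones from -0.12 with normexp to -0.29 with the probe length trend removed.

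The fourth comparison was of the single X chromosome of males with the autosomes. The 1190 X regions averaged 0.09 ± 0.04 and the 27675 autosomal regions -0.05 ± 0.02, so X regions were higher by 0.14 ± 0.04 (n = 3, exact sign-flip permutation p = 0.25, the smallest possible), but with the series matrix values they were lower, at -0.09 ± 0.003. On the X, 30.8% of regions were higher than the median and 27.6% lower, against 27.8% and 38.6% on the autosomes. X probes were dimmer, with a median log2 input signal of 8.35 against 9.31 and input above background on all arrays in 48.6% against 65.8% of probes. Over probes with input above background X regions were higher both with the processed signals (0.14 ± 0.004) and with the series matrix values (0.09 ± 0.01). With normexp the difference was 0.08 ± 0.01.

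**Figure D3:**
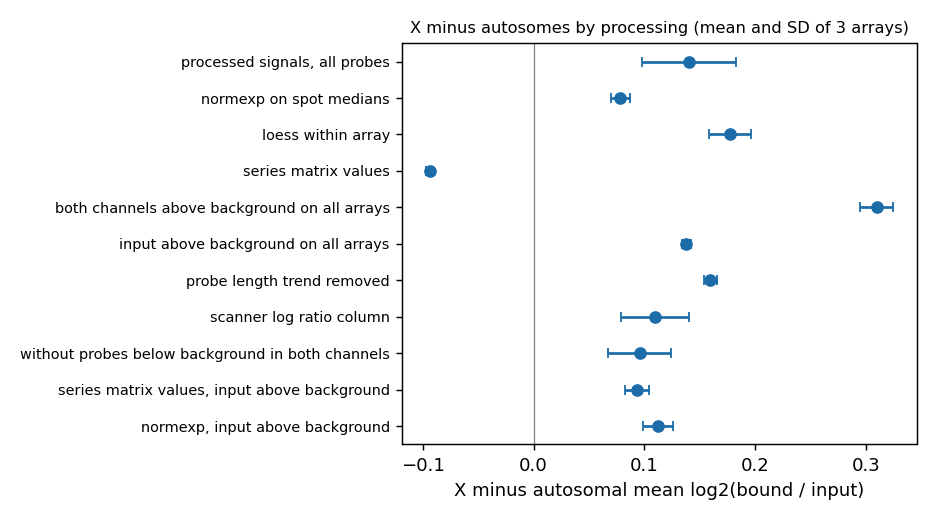
X minus autosomal mean log2 ratio of bound over input DNA over tiled regions (x axis) for each way of processing the arrays (y axis). Points are means and bars SDs of 3 arrays; all values lie above 0 except that of the series matrix with all its probes, at -0.09, and the value of 0.31 comes from a selection that also acts on the bound signal, the numerator of the ratio.

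Chromosome 13 had the lowest mean of all chromosomes, -0.16 ± 0.02 over 1025 regions, also with the series matrix values (-0.11 ± 0.02) and over probes with input above background (-0.35 ± 0.12, where chromosome 19 was next at -0.29 ± 0.10). Chromosome 19 was at -0.14 ± 0.01 and chromosome 18 at -0.12 ± 0.02. The highest autosome was chromosome 15 at 0.01 ± 0.04, with 33.9% of its 1065 regions higher than the median against 23.6% on chromosome 13. The Y chromosome had 15 regions with a mean of 0.27 ± 0.07, and was at -0.02 ± 0.04 with the series matrix values. Over probes with input above background every chromosome had a lower mean, and the Y, with 9 regions, was at 0.03 ± 0.13. These values kept the zero of the full arrays, so the shared fall goes with the choice of probes and is no difference between chromosomes. Differences between single chromosomes were not tested.

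**Figure D4:**
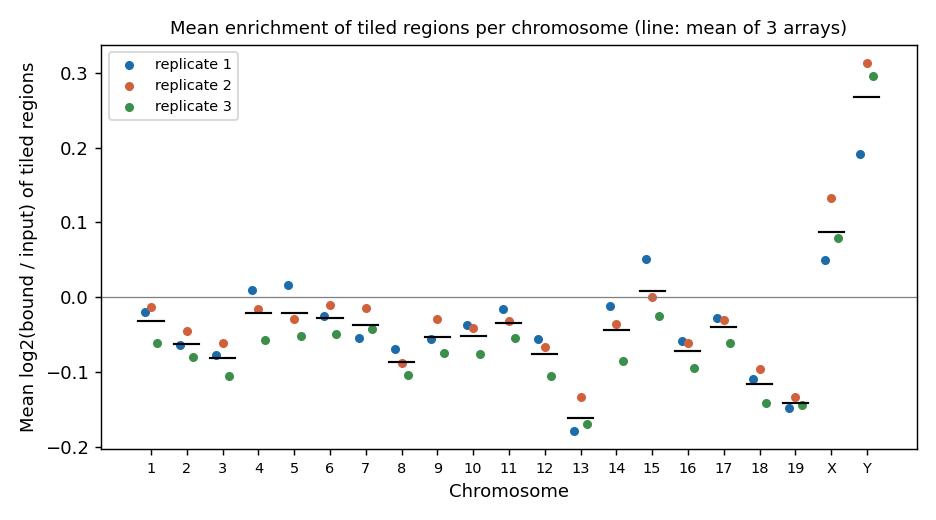
Mean log2 ratio of bound over input DNA over the tiled regions of each chromosome (y axis), by chromosome (x axis). Points are the 3 replicates and lines their means, with chromosome 13 lowest at -0.16 and the X at 0.09, although the X lay below the autosomes with the series matrix values.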

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

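Filters on the input signal, the probe length trend, the scanner's log ratio column, the region definitions, array weights, and every alternative for tiled regions, centre minus edges and length classes were chosen after the data were seen. Region counts stayed within 1.5 times of 8066 higher and 11003 lower in every alternative run except centring on the mode, which gave 2500 and 22219, because the zero point moved up. The same centring gave 31931 higher and 168205 lower probes. The series matrix values gave 60821 lower probes. With both channels above background and the arrays centred again, 173292 probes were tested. Of these probes, 58451 were higher and 60607 lower. Centre minus edges gave 1378 and 2610 under this filter, in which fewer regions kept enough probes to be tested. With 1 replicate left out, higher probes numbered 42611 to 63220, lower probes 58484 to 86474, regions with a higher centre 1525 to 2415 and X minus autosomes was 0.12 to 0.16. A minimum log2 ratio of 0.5 removed no call at probes or in centre minus edges. The mean of centre minus edges (-0.29) kept its sign throughout and was -0.13 with normexp, -0.19 with normexp and input above background, and -0.40 with input above background. Short minus standard regions (0.17) also kept its sign and was 0.077 with normexp, 0.074 with loess, 0.20 with the series matrix, 0.35 with both channels above background, 0.30 with input above background, 0.24 without probes below background in both channels, and 0.31 with the series matrix and input above background. Long minus standard regions (-0.26) kept its sign too and was -0.117 with normexp, -0.135 with normexp and input above background, -0.212 with loess, -0.134 with the series matrix and -0.290 with the probe length trend removed. X minus autosomes (0.14) reversed to -0.094 with the series matrix. It was 0.079 with normexp, 0.31 with both channels above background (a filter that selects on bound signal), 0.10 without probes below background in both channels and 0.093 with the series matrix and input above background, so the reversal came with dim probes. The other causes were not tested. For the 20 named regions all 279 values under alternatives kept their direction and stayed past the threshold, though not their size. The same held for all 266 values of the 20 named centre contrasts. These items were chosen as extremes of the same arrays, so a reversal was unlikely. Where too few probes were left there was no value. With both channels above background 16 regions and 9 centre contrasts had a value, and with at least 8 probes per region 3 regions had one. Not run, for want of sequence or annotation of the build, were the promoter windows, the probe GC trend, centring on CpG-poor probes, matched random lists, the estimated set correlation, and the alternatives of the promoter, start site, CpG class, TATA and gene list results. The scanner's signal-to-noise for bound DNA (4.44 to 9.93) was outside the accepted range, and values of regions with bound DNA near background are limits rather than levels.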

Other observations

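The tests in this part were chosen after the results were seen, except the numbers of probe calls and the X minus autosome difference with the series matrix, which were fixed before. Enrichment was weakly shared over distances longer than a tiled region. Of 1357 windows of 500 kb with at least 8 regions, the highest were on chromosome 10 from 116000001 to 116500000 (8 regions, 1.10 ± 0.17, SD, n = 3 arrays) and on the X chromosome from 8500001 to 9000000 (13 regions, 1.09 ± 0.04) and from 70000001 to 70500000 (13 regions, 0.97 ± 0.11). Windows with many regions were also among the 10 highest, on chromosome 9 from 110500001 to 111000000 (23 regions, 0.80 ± 0.15) and on chromosome 15 from 101500001 to 102000000 (22 regions, 0.79 ± 0.12). The lowest lay on chromosome 8 from 22500001 to 23000000 (12 regions, -1.08 ± 0.25) with its neighbour from 22000001 to 22500000 (14 regions, -1.02 ± 0.29), on chromosome 1 from 85000001 to 85500000 (8 regions, -1.06 ± 0.08) and on chromosome 2 from 175000001 to 175500000 (12 regions, -1.03 ± 0.07). On chromosome 6 the window from 52000001 to 52500000 was at -0.96 ± 0.04 over 17 regions. All of these had limma adjusted p values of 5.62e-07 or lower and the same sign on 3 of 3 arrays. That test asks whether a window's mean repeats over arrays, not whether its regions cluster. Means at least 0.6 above the array median occurred in 24 windows, against at most 13 in 100 shuffled orders of regions. Means at least 0.6 below it occurred in 34, against at most 13. The ranking of windows is that over all probes and changed with input above background. Among the 10 highest windows, that on the X from 8500001 then led at 1.37 ± 0.14, against 1.18 ± 0.25 on chromosome 10. A window on chromosome 6 from 145500001 to 146000000 (1.10 ± 0.16) lay above that on the X from 70000001 (0.92 ± 0.12). In the 2 windows of chromosome 8 only 52.5% and 45.9% of probes were above background in both channels on at least 1 array. Among the 10 lowest windows, that from 22000001 was lowest with input above background, at -1.56 ± 0.15. Windows on chromosomes 7 from 7000001 (-1.44 ± 0.10) and 4 from 143500001 (-1.23 ± 0.06) then lay below those on chromosomes 1 (-1.12 ± 0.13) and 2 (-1.04 ± 0.04).

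Within regions, the correlation of 2 probes across probe pairs fell with their distance, from 0.57 ± 0.07 (SD over 3 arrays) under 100 bp to 0.34 ± 0.04 at 200 to 400 bp and 0.13 ± 0.01 at 1000 to 1400 bp. Probe pairs are not independent replicates. Probes of 45 nt averaged 0.14 ± 0.16 and those of 57 nt -0.48 ± 0.04. Probes of 60 nt averaged -0.06 ± 0.19, and only 23.8% of them had input above background on all arrays, over which they averaged -0.58 ± 0.07.

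The lower centre of standard regions was weighed against 2 technical explanations. Over probes with both channels above background on all arrays the centre stayed below the edges by -0.298 (SD 0.03), under a filter that selects on bound signal, and over probes with input above background by -0.40, which argues against signals near background as the whole cause. With normexp the difference was smaller, at -0.13 (SD 0.04), and at -0.19 (SD 0.05) with input above background. That alternative also added an offset and used spot medians in place of processed signals. These changes were not made separately, so the smaller size cannot be assigned to the background correction itself. With the probe length trend removed the difference was -0.246 (SD 0.04), which argues against probe length. GC content and the number of CpGs per fragment were not tested and stay open, and with 1 group no biological explanation was tested.

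The higher mean of X regions, which reversed in the series matrix at -0.09, was weighed against dim probes of the single X and against probe length. Over probes with input above background, the smaller of the differences from the processed signals and the series matrix was 0.0935 (SD 0.01), above 0 by more than 2 SD. Probes with dim input thus do not account for the whole excess, although they go with the reversal. Without probes below background in both channels the excess fell from 0.14 to 0.10 (SD 0.03). Probes dim only in the bound channel remained under these filters, so their part was not settled. With the probe length trend removed over probes with input above background, the difference was 0.154 (SD 0.004). With probes split into 10 equal groups by input signal, the excess was 0.01 ± 0.04 in the dimmest group, with 3143 X probes. It turned to -0.03 ± 0.06, -0.02 ± 0.01 and -0.04 ± 0.01 in the next 3, and was 0.51 ± 0.03 in the brightest, with 832 X probes. Input is the denominator of the ratio and was lower on the X, so these groups need not match like probes. Sequence composition and cross-hybridisation stay open, and no biological explanation was tested.

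Adjacent regions 2 to 50 kb apart were weakly correlated, with r = 0.17 (SD 0.02 over 3 arrays) over 16535 pairs. The correlation was at most 0.016 in 100 shuffled orders within chromosomes. With probe length and input signal regressed out, r was 0.168 (SD 0.006), and over probes with both channels above background it was 0.148 (SD 0.005), so neither probe length and input signal nor signals near background account for it. Windows spread with an SD of 0.30 against at most 0.23 in the shuffled orders. Shared base composition of neighbouring sites was not tested and stays open. No biological explanation was tested.

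Exchanging bound and input within arrays gives only 4 splits with 3 arrays, too few for a share under 0.05. Only the real split, 1 of 4, reached its own numbers of calls by limma, which were 188260 for probes, 19069 for regions and 8816 for centre minus edges. The other splits gave at most 0 calls, and at an unadjusted p under 0.05 at most 869, 5 and 22. In those splits the ratios of 1 array were reversed, which raises the variance of every feature on which the arrays agree. Their few calls follow from that agreement, so this comparison cannot decide whether the calls arose by chance.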
